A study of Mus musculus with 11 samples.

How the data were processed

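Adrenocortical cells positive for green fluorescent protein were sorted from the adrenal glands of mouse embryos, and RNA of each mouse was amplified linearly, labelled with Cy3 and hybridised to a single-colour Agilent mouse array, per the labels. Genotype, sex, age and replicate number came from the labels, and slide from the array identity in the files. Which promoter drove the fluorescent reporter is not given in the sources used here.

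The deposited scanner files hold the intensity of each spot, from Agilent Feature Extraction, with background subtraction done by that program in the processed signal, per the file headers. The headers name version 10.1.1.1 for the arrays of slides 1 and 2 and version 10.5.1.1 for slide 3, while the submitters' processing notes name only 10.5.1.1. The deposited series table holds log2 values by the authors, and how they were scaled is not given in the sources used here. Each column was set against the scanner values of its array: the table matched log2 processed signal minus the array's 75th percentile, centred on each probe's median, within 0.01 for 99.8% of probes on every array, with column medians between −0.166 and 0.902. The deposited flags used here mark spots that are well above background, outliers or saturated.

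Of 45018 spots per array, 43379 were not controls. Between 77 and 164 spots per array were left out as outliers, and 0 probes were saturated. Spots of 1 probe were averaged as log2 processed signal, and each array's 75th percentile over the 41174 probes was subtracted. Probes were named through the accession in the files and a RefSeq gene table of the assembly GRCm38.p6, whose coordinates were not used because the files name no build: 25377 probes had a symbol, for 17427 genes, and 15797 had none and were tested under their own name. A gene was taken from its probe with the highest mean over all arrays and tested if that probe was well above background on at least 4 of the 11 arrays. Of 45 named genes past the threshold with several probes, 36 had all probes in the same direction.

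Genotypes were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with genotype and slide as terms (7 residual degrees of freedom; slide 3 holds 1 genotype and enters only the variance), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each array came from a different mouse. A gene not above background on any array of 1 genotype has only a bound on its fold change. Gene lists, fixed before the data were examined together with the groups, fits and most of the alternatives, were tested with camera at a preset correlation of 0.01 and a minimum of 5 tested members, and again with an estimated correlation and with fry. Of 533 list genes 517 were on the array. The lists covered steroid synthesis, adrenal transcription factors, ACTH signalling, 4 aspects of cholesterol and lipid handling, macrophages and other cell types, inflammation, stress responses, cell cycle, adrenal zones, respiration, lysosomes and matrix, and a sex-linked list served to check the labels. Genes named in the text were, by a rule fixed at the same time, Star, the 10 highest and 10 lowest fold changes past the threshold with an informative symbol, not sex-linked and of the same direction within slides 1 and 2, and up to 4 members of each list with the smallest p. Exceptions named after their values were seen are Cd163, Srd5a1, Hsd3b1, Spi1, Lyz2, Ctss, Cyp21a1, Cyp11a1, Th and Dbh. Results for some members of the lists are not reported here. Array quality was compared by exact permutation.

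On simulated data drawn from the real means, residual spreads and design, over 20688 genes with 200 changed, the fit called 0% of genes changed 2-fold, 22.4% of those changed 4-fold and 48.5% of those changed 8-fold, with 4 false calls, and 0 calls when no gene was changed. The simulated errors were independent between genes and had the same spread on every array. Estimated weights of the real arrays ran from 0.17 to 4.70, so these counts of false calls do not carry over to them.

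Alternatives concerned the slide term, sex, the replicate number as a block, background, scaling, the filter on dim probes, separate probes, the series table, a 2-fold minimum, the variance prior, array weights, outlier spots and each array left out. The normexp correction, with an offset of 50, was to start from mean spot signals; the deposited files have no such column, so it used median spot signals. The replicate numbers were not established as pairs. Random blocks used statmod 1.5.0, tables version 1.17.8 of data.table, pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9 in Python 3.11.15.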

Results

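Gene expression was measured in fluorescent adrenocortical cells sorted from fetal mouse adrenal glands, to compare 4 mice lacking Star with 7 wild-type mice. Star encodes the steroidogenic acute regulatory protein, which carries cholesterol into mitochondria for the first step of steroid synthesis. Each of the 11 single-colour arrays held amplified RNA of 1 mouse late in gestation, and the cells had been taken by flow cytometry for green fluorescent protein. The arrays lay on 3 slides. Slide 1 held 2 wild-type and 2 knockout arrays, slide 2 held 1 wild-type and 2 knockout arrays, and slide 3 held 4 wild-type arrays. With slide as a block, every fitted difference between genotypes rests on the 4 knockout and 3 wild-type arrays of slides 1 and 2, and the 4 arrays of slide 3 add only to the estimate of the spread. Wild-type array 3, the only wild-type array on slide 2, had the lowest 75th percentile of the signal, 115, and the lowest median correlation with the other arrays, 0.877. All 4 knockout arrays were labelled male, and the wild-type arrays were labelled 3 male and 4 female. Between 19070 and 26414 of 41174 probes per array were well above background, and the number of arrays limits the precision of every comparison below. Levels are log2 signals relative to the array's 75th percentile, and each level belongs to its own probe.

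The transcript of Star itself was lower in all 4 knockout arrays than the mean of the wild-type arrays, with a difference of −4.70 ± 0.93 on the log2 scale (SE, 4 against 3 arrays on slides 1 and 2). Over all slides, wild-type levels were 5.75 ± 1.82 (SD, n = 7) and knockout levels 2.37 ± 0.73 (SD, n = 4). The difference was −4.37 within slide 1 and −5.20 within slide 2. Over all genes tested it narrowly missed the threshold, at a limma adjusted p of 0.0559, and the lowest wild-type level, 3.21 in array 6, lay below the highest knockout level, 3.27 in array 4. Both Star probes were lower in the knockout arrays. Over 35 alternatives the adjusted p ran from 0.00242 to 0.512, and 12 of them passed. The probe stayed well above background on every knockout array, and with neither the deleted part of the gene nor the probe's position known here, it gives a limited check of the genotype labels.

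The comparison of genotypes asked which other transcripts differ when Star is missing. Slc32a1, the vesicular transporter of GABA and glycine, was at least 224-fold higher in the knockout arrays, and Gpnmb, a transmembrane glycoprotein of macrophages and pigment cells, rose by 7.93 ± 0.79 on the log2 scale (SE, 4 against 3 arrays). Several of the others are known from macrophages or from inflammation. Cd5l, a protein secreted by macrophages, rose by 6.12 ± 0.90, the chemokine Ccl8 by 5.81 ± 0.75, the interleukin 1 receptor antagonist Il1rn by 5.52 ± 0.99 and osteopontin, Spp1, by 5.37 ± 0.53. Among the genes that fell were Akr1c18, an enzyme that inactivates progesterone and marks the mouse adrenal X-zone, by 6.03 ± 1.15, and Nr0b1, the nuclear receptor DAX1, by 5.58 ± 0.89.

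Of 20739 genes and unnamed probes tested, 173 passed an adjusted p of 0.05 in limma, 125 of them higher and 48 lower in the knockout arrays, and 3831 had an unadjusted p under 0.05. The share of higher genes among those past the threshold, 72.3%, varied with the fit. It was 54.3% with array weights, 55.8% over genes above background on all 11 arrays and 95.8% without wild-type array 1. Gene symbols were known for 134 of the 173, of which 104 were higher and 30 lower. In the fitted values all 173 differed by 2-fold or more and had the same direction within slide 1 and within slide 2. Over all slides, the values of the 2 genotypes did not overlap for 1526 of the tested genes and probes. The share expected by chance, 0.606%, holds only if all arrays are interchangeable. A slide held only wild-type arrays and all knockout arrays were labelled male, so slide or sex could also raise the count. The 0.606% therefore does not show how many of the 1526 are due to genotype. Of the 173 past the threshold, 155 were among the 1526, but both were chosen on the same values. For 18 of those higher, no wild-type array of slides 1 and 2 was above background, and for 4 of those lower no knockout array was, so their fold changes are known only as bounds.

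Other genes among the 10 with the highest fitted fold changes were Car6, a secreted carbonic anhydrase, the interleukin 7 receptor Il7r, Atp6v0d2, a subunit of the vacuolar proton pump, and Npr2, the receptor of C-type natriuretic peptide. The place of Atp6v0d2 among these 10 is not settled, since its fold change is known only as a bound. Car6 was not well above background on any wild-type array and was at least 43.0-fold higher in the knockout arrays (adjusted p = 0.000148, limma), and Atp6v0d2, likewise not above background in wild-type arrays, was at least 9.67-fold higher (adjusted p = 0.00453). Such a bound, taken over slides 1 and 2, replaces each signal of the genotype not above background by the lowest signal above background on that array, or keeps the probe's own signal where that was higher. It bounds the fitted mean difference and leaves out the sampling error. Il7r rose by 5.55 ± 0.88 and Npr2 by 5.07 ± 0.73. Slc32a1 was above background on wild-type array 4 of slide 3 alone, and so on none of the wild-type arrays that enter its difference. Of the 7 wild-type arrays, Gpnmb and Ccl8 were above background on 2 and Il7r on 1, so their fitted changes rest on dim wild-type signals. Il1rn and Npr2 were not above background on wild-type array 3, the only wild-type array of slide 2. Their differences there were 6.90 and 6.64, against 4.59 and 4.03 within slide 1. Of several probes, 1 of 2 for Il1rn and 2 of 3 for Npr2 were higher in the knockout arrays.

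Genes that fell also included Tmem200a at −3.72 ± 0.60, Mpped2 at −3.40 ± 0.53, the small GTPase gene Rab33a at −3.37 ± 0.63 and Ecrg4 at −3.28 ± 0.52. The kinase gene Prkd1 was at −3.07 ± 0.47, Nckap5 at −2.89 ± 0.48 and the heparan sulfate endosulfatase gene Sulf1 at −2.87 ± 0.55 (SE, 4 against 3 arrays). The neuropeptide Y receptor gene Npy2r was not well above background on any knockout array and was at least 2.38-fold lower there (adjusted p = 0.0275). The adjusted p was 0.0495 for Akr1c18 and for Sulf1, 0.0478 for Rab33a and 0.0275 for Nr0b1, against 0.00146 for Slc32a1 and 0.00347 for Gpnmb and for Spp1. With sex as a further term, none of these 10 lower genes passed, nor did Cd5l, Ccl8, Il7r, Il1rn and Npr2 among the higher ones. The one wild-type array of slide 2 was labelled female and all knockout arrays male. With wild-type array 4, whose sex label is in doubt, left out as well, Nr0b1, Ecrg4 and Npr2 passed.

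**Figure D1:**
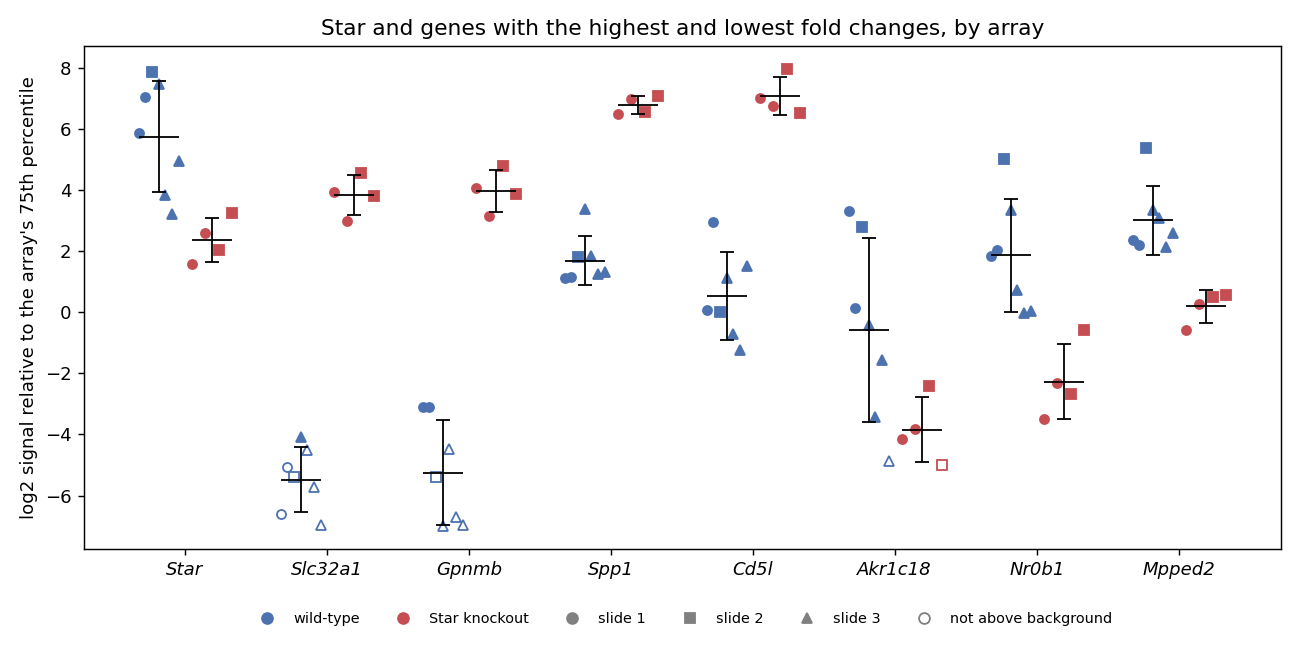
Log2 signal relative to each array's 75th percentile (y axis) for Star, 4 of the genes that rose and 3 that fell (x axis), with 1 point per array, shape giving the slide, open points not well above background, and bars the mean ± SD of 7 wild-type and 4 knockout arrays. Star levels ran from 3.21 to 7.86 in wild-type and from 1.58 to 3.27 in knockout arrays.

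The number of genes past the threshold depended on single arrays: it was 24, 35, 10, 565 and 106 without wild-type arrays 1, 2, 3, 4 and 7, and 20, 52, 31 and 29 without knockout arrays 1 to 4. It was 0 within slide 1 and 0 within slide 2 (limma; 3856 and 7489 genes at an unadjusted p under 0.05), 594 without the slide block, 469 with slide as a random block and 28 with sex as a further term, 25 of them higher and 3 lower. Of the 20 genes with the highest and lowest fold changes, 3 passed whichever array was left out, Slc32a1, Car6 and Atp6v0d2. None of the wild-type arrays of slides 1 and 2 was above background for these 3, so their wild-type spread is that of background signals and their passing says little about stability.

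Markers of macrophages and other myeloid cells were higher as a list. The median of 24 tested members was 2.92 higher in the knockout arrays on the log2 scale, 1.90 within slide 1 and without wild-type array 3, and 4.22 within slide 2 (camera, adjusted p = 9.25e-17). With an estimated correlation between genes, the adjusted p was 0.147. Members that passed over all genes were Gpnmb, Trem2 with 3.92 ± 0.50, the lysozyme gene Lyz1 with 4.48 ± 0.63, Cd5l and the transcription factor gene Spi1, 5 of 24, and adjusted over the list alone 20 were higher and 1 lower. The lower member was the haemoglobin scavenger receptor gene Cd163, at −4.06 ± 1.44 (adjusted p = 0.192 over all genes), which was −6.56 within slide 1 and −0.32 within slide 2. Spi1 was not above background in wild-type arrays, and with it at its bound the median was 2.85.

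Genes of lysosomes and sterol export were also higher. All 19 tested members of the lysosome and autophagy list had a higher mean in the knockout arrays, with a median of 1.28 (camera, adjusted p = 2.87e-11; adjusted p = 0.0820 with an estimated correlation). The protease gene Ctsd rose by 3.37 ± 0.59 and Npc2, which binds cholesterol inside lysosomes, by 1.98 ± 0.36, and adjusted over the list alone 11 members were higher. Targets of the liver X receptors, which respond to oxysterols, had a median of 1.16 over 18 members (camera, adjusted p = 3.31e-05; adjusted p = 0.0648 with an estimated correlation). The phospholipid transfer protein gene Pltp rose by 4.30 ± 0.43 and the sterol exporter gene Abcg1 by 3.46 ± 0.63, and adjusted over the list alone 10 were higher and 1 lower. Without wild-type array 3, Ctsd was at 2.06 (adjusted p = 0.139) and Abcg1 at 2.08 (adjusted p = 0.197). Ctsd was also counted among the genes of lipid-laden macrophages in a later contrast. Whether these lists moved apart from the macrophage markers, and in which cells, was not tested.

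Lists of inflammatory genes, and 3 of the stress-response lists, were also higher. Whether these lists, and the matrix list given last, moved apart from the macrophage markers was not tested. Chemokines, cytokines and NF-kB targets had a median of 1.68 over 22 members (camera, adjusted p = 1.92e-06; 0.363 as adjusted p with an estimated correlation); Il1rn passed over all genes, and adjusted over the list alone 5 were higher. Complement and antigen presentation genes had a median of 1.44 over 20 members (adjusted p = 2.05e-05; adjusted p = 0.363 with an estimated correlation), and 0 passed over all genes but 3 over the list alone, H2-D1, Cd74 and H2-Ab1. Without wild-type array 3 that median was 0.94, H2-D1 was at 2.05 in place of 3.27 and H2-Ab1 at 2.62 in place of 4.22. Immediate early genes had a median of 0.71 over 18 members (adjusted p = 4.60e-05; adjusted p = 0.363 with an estimated correlation), with 4 higher adjusted over the list alone. The p53 and cell death list had a median of 0.81 over 18 members (adjusted p = 0.000229; adjusted p = 0.147 with an estimated correlation), with 5 higher adjusted over the list alone, among them Bbc3 with 2.44 ± 0.57. Its median was 0.37 without wild-type array 3 and within slide 1, and 1.35 within slide 2. In the unfolded protein and integrated stress response list, with a median of 0.63 over 18 members (adjusted p = 0.00124; adjusted p = 0.292 with an estimated correlation), the pseudokinase gene Trib3 rose by 4.12 ± 0.48 and 3 were higher adjusted over the list alone. The extracellular matrix list had a median of 1.15 over 19 members (adjusted p = 0.000366; adjusted p = 0.363 with an estimated correlation), with Spp1 past the threshold over all genes and 6 adjusted over the list alone.

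Lists that were lower in the knockout arrays held genes of proliferation, respiration and adrenal zones. Cell cycle genes had a median of −1.10 over 24 members (camera, adjusted p = 1.92e-06; adjusted p = 0.292 with an estimated correlation); 0 passed over all genes and 13 were lower adjusted over the list alone, for example the replication helicase gene Mcm6 at −2.01 ± 0.42 and the topoisomerase gene Top2a at −2.04 ± 0.50. The cell cycle median was −0.63 without wild-type array 3 and within slide 1, and −1.87 within slide 2, and without that array Mcm6 was at −1.22 and Top2a at −1.24. Respiratory chain genes had a median of −0.73 over 27 members (adjusted p = 0.00112; adjusted p = 0.480 with an estimated correlation), and 0 passed over all genes or over the list alone. The respiratory chain median was −0.34 without wild-type array 3 and within slide 1, and −1.32 within slide 2. Fetal zone and X-zone markers had a median of −2.06 over 6 members (adjusted p = 0.00967; adjusted p = 0.363 with an estimated correlation); Akr1c18 and Nr0b1 fell, and 3 were lower adjusted over the list alone. In the zona glomerulosa, WNT and hedgehog list, with a median of −1.17 over 17 members (adjusted p = 0.0127; adjusted p = 0.292 with an estimated correlation), the WNT target gene Axin2 fell by 2.86 ± 0.44, and 3 were lower adjusted over the list alone. The hedgehog ligand gene Shh was not above background in knockout arrays and did not pass over all genes (limma, adjusted p = 0.0819). Its bound on the fitted difference was 12-fold lower there. With 3 members at their bounds, the median stayed at −1.17.

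Among cell types other than the sorted one, Schwann cell precursor markers had a median of 1.51 over 7 members (adjusted p = 0.00990; adjusted p = 0.480 with an estimated correlation), capsule and stromal markers of 0.93 over 16 (adjusted p = 0.0166; adjusted p = 0.587 with an estimated correlation), endothelial markers of 0.63 over 15 (adjusted p = 0.0451; adjusted p = 0.587 with an estimated correlation) and erythroid markers of −1.003 over 11 (adjusted p = 0.0360; adjusted p = 0.484 with an estimated correlation). No member of these 4 lists passed over all genes, and adjusted over the list alone only Acta2, smooth muscle actin, of the capsule list did, at 2.10 ± 0.48. With 2 Schwann cell and 1 capsule marker at their bounds, these medians were 0.97 and 0.81. With sex as a further term none of the 4 lists passed, and with wild-type array 4 left out as well all but the erythroid list did. Single arrays decided 3 of these calls. The adjusted p of the capsule list was 0.103 without wild-type array 2 and 0.0707 without knockout array 3, and its median was 0.50 without wild-type array 3 and 0.53 without knockout array 3. That of the erythroid list was 0.923 without wild-type array 3, where its median was −0.082, and 0.0710 and 0.0563 without knockout arrays 3 and 4. That of the endothelial list was 0.119, 0.817 and 0.0510 without wild-type arrays 2, 3 and 4, and 0.0517, 0.101 and 0.0563 without knockout arrays 2, 3 and 4. The endothelial median was 1.13 without wild-type array 1 and 0.092 without wild-type array 3. Chromaffin and sympathoblast markers had a median of −0.65 over 18 members (adjusted p = 0.115), and passed without wild-type arrays 1, 3 or 4 or knockout array 3, at 0.0452, 0.0395, 0.0438 and 0.0143. The chromaffin median was −0.39 without wild-type array 2 and −0.37 without knockout array 4. The adrenaline-forming enzyme gene Pnmt, in that list, differed by −5.54 ± 1.44 (adjusted p = 0.107), with levels between −4.16 and −3.44 in knockout and between −1.04 and 5.34 in wild-type arrays. Kidney and liver markers had a median of 0.90 over 11 members (adjusted p = 0.205; 0.0264 without wild-type array 3) and gonadal somatic markers of −0.27 over 9 (adjusted p = 0.852).

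**Figure D2:**
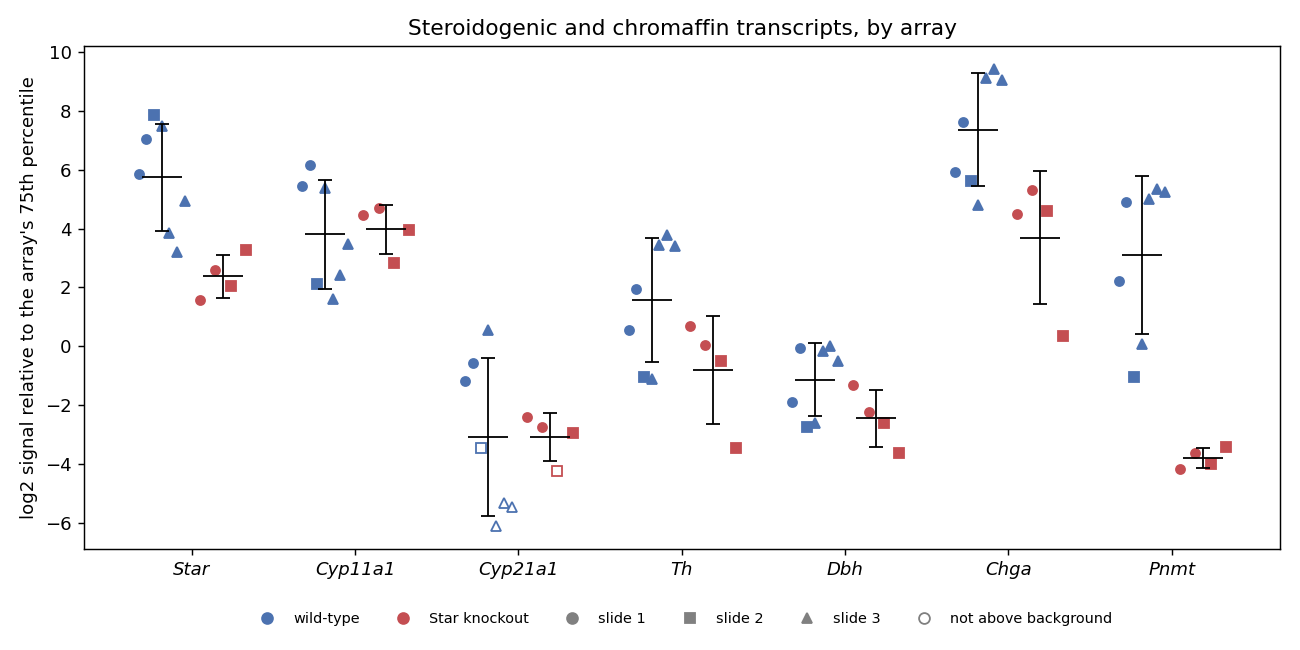
Log2 signal relative to each array's 75th percentile (y axis) for 3 steroidogenic and 4 chromaffin transcripts (x axis), with 1 point per array, shape giving the slide, open points not well above background, and bars the mean ± SD of 7 wild-type and 4 knockout arrays. Pnmt lay between −4.16 and −3.44 in knockout and between −1.04 and 5.34 in wild-type arrays.

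Genes of steroid synthesis as a list did not pass. The 17 tested members had a median of −1.34 (camera, adjusted p = 0.163; 0.0481 without wild-type array 4). The median was −0.64 without wild-type array 3 and within slide 1, and −0.80 within slide 2. In this list 0 passed over all genes, and adjusted over the list alone 4 were lower and 2 higher: Star, Hsd11b1, Srd5a1 and Hsd3b1 below, Stard3 and Cyb5a above. Cholesterol synthesis genes had a median of −0.62 over 24 members (adjusted p = 0.118; 0.0417 and 0.0261 without wild-type arrays 1 and 3), 0 passed over all genes and 2 were lower adjusted over the list alone, among them Acat2 at −1.59 ± 0.40. Without wild-type array 3 Acat2 was at −0.97 and Cyb5a, in the steroid synthesis list, at 0.62 in place of 1.07. The cholesterol synthesis median was −0.96 without wild-type array 1, −0.38 without knockout array 1 and −1.08 without knockout array 2. Cholesterol uptake and transport genes had a median of −0.054 but a mean of 0.33 over 18 members (adjusted p = 0.141, direction up; 0.0193 without wild-type array 3), and in the lipid droplet list, with a median of 0.26 over 19 members (adjusted p = 0.0903; 0.0246 without wild-type array 2), Hilpda rose by 2.94 ± 0.53. Medians were −0.17 for adrenal transcription factors (adjusted p = 0.997), 0.20 for ACTH and cAMP signalling (adjusted p = 0.361), 0.36 for glucocorticoid-responsive genes (adjusted p = 0.468) and 0.21 for NRF2 targets (adjusted p = 0.205; 0.0261 without wild-type array 3). With single arrays left out, the glucocorticoid-responsive median ran from 0.041 to 0.49 and the NRF2 median from 0.064 to 0.59. The hypoxia and glycolysis list had a median of −0.050 and a mean of −0.021 while camera placed it higher than other genes, at an adjusted p of 0.708; the gonadal list had a mean of 0.18 and was also placed higher.

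Of 29 lists tested, 17 passed with the preset correlation, 12 higher and 5 lower, and the medians of all 17 had the same sign within slide 1 and within slide 2. With an estimated correlation 0 of the 29 passed, and with fry, which asks whether a list's own genes move on balance one way, 8 passed.

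**Figure D3:**
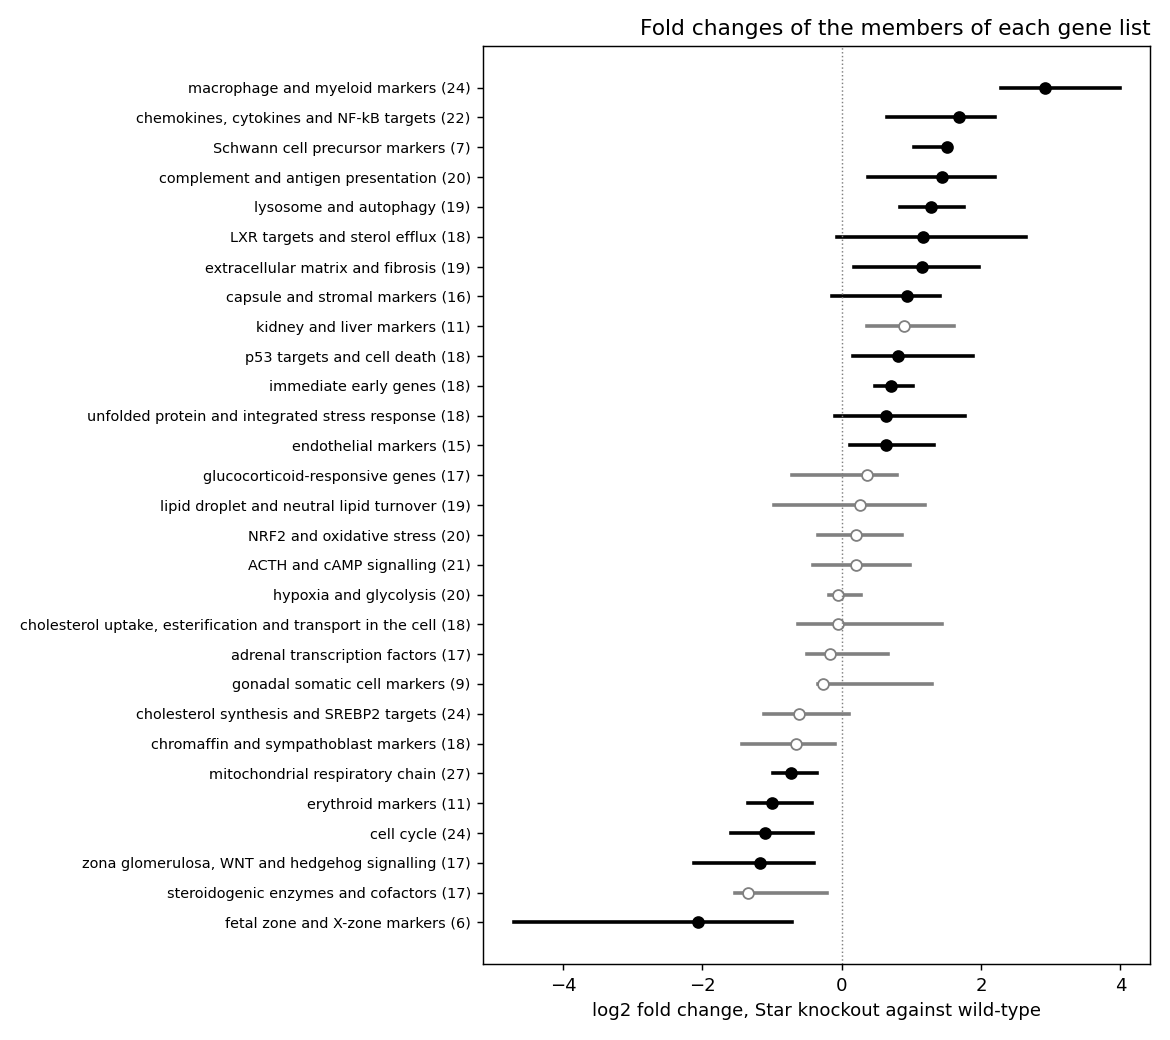
Median (point) and quartiles (line) of the log2 fold changes of each list's members, Star knockout against wild-type (x axis), by gene list with the number of members tested (y axis). Black marks the 17 lists past the threshold with the preset correlation, from −2.06 for fetal zone and X-zone markers to 2.92 for macrophage markers (1.90 without wild-type array 3), and grey with open points the others.

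Sex was compared across the same arrays, with genotype and slide as terms. No gene passed (0 in limma; 1544 genes at an unadjusted p under 0.05). The Y-linked genes Ddx3y and Eif2s3y were at 2.70 and 2.70 in the wild-type array 4, labelled female, and ran from 2.26 to 3.32 and from 2.36 to 2.62 in the 7 male-labelled arrays. In the other female-labelled arrays, 3, 5 and 6, both lay at −5.24 or below and were not above background. Without array 4, 4 genes passed, 3 of them Y-linked, and without array 3, 3 genes passed. Xist, transcribed from the inactive X, was above background on the wild-type array 3 alone, so its probe gave no check of the other arrays labelled female.

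None of 3 measures of array quality passed a test between genotypes, although the means of 2 of them differed by more than the wild-type SD. On average 22254 ± 2574 probes were well above background in wild-type and 25030 ± 1253 in knockout arrays (SD, n = 7 and 4; exact two-sided permutation test over 330 splits, p = 0.0848), and over slides 1 and 2 the exact p was 0.457. The median correlation with the other arrays was 0.914 ± 0.020 in wild-type and 0.931 ± 0.0059 in knockout arrays (SD, n = 7 and 4; exact permutation p = 0.118), and the 75th percentile of the signal was 297 ± 129 and 455 ± 221 (SD, n = 7 and 4; exact permutation p = 0.173). These permutations did not keep slide. The 75th percentile was 706 and 544 in knockout against 438 and 463 in wild-type arrays on slide 1, and 378 and 190 against 115 on slide 2. Each knockout array also had more probes well above background than every wild-type array of its slide. The median correlations overlapped on slide 1.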

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

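The random lists and the splits drawn from all arrays were planned, and the splits within slides and all other tests of the macrophage and Y-linked patterns were chosen after the result was seen. A lone array was looked for in 66 groups of values, of which about 1 in 20 would stand apart by chance, and 8 did.

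Macrophage transcripts stood higher in the knockout arrays, and how far the sort removed macrophages is not known here. Lyz2 was at 6.14 ± 0.79 in wild-type and 8.61 ± 0.57 in knockout arrays, and Ctss at 5.48 ± 1.45 and 8.49 ± 0.45 (SD, n = 7 and 4). Brighter knockout arrays are argued against, since 0 of 10000 random lists matched on mean signal reached the median of 2.92 (highest 0.84; the median was 1.90 without wild-type array 3). The macrophage mean exceeded that of 5 other cell type lists by 2.74 ± 0.55 on the log2 scale (SE), which argues against an equal rise of these lists. Medians of the 5 ran from −1.003 for erythroid to 1.51 for Schwann cell precursor markers. A lower share of steroidogenic cells would raise them alike only if the sorted cells made none of the markers and none lay near background. That was not established, so a lower share with unequal changes is not excluded. More macrophages in an unchanged state would move all members by 1 factor only if no other cells made them and none lay near background. Neither condition was established. A first contrast, of 7 genes of lipid-laden macrophages (3.22 ± 0.35) with 11 genes shared by macrophages (3.07 ± 0.79), was undecided at 0.15 ± 0.61. Its filter on wild-type signals above background left out the lipid-laden markers Gpnmb, at 7.93, and Atp6v0d2, at least 9.67-fold higher. A test of the spread, adopted only after that contrast, found 0 of 10000 draws of the errors alone to spread 17 members as widely. It rests largely on Cd163, without which 482 of the 10000 draws did. Unequal changes could also arise with unchanged macrophages where those conditions fail, so the test does not decide the question. More macrophages in an unchanged or a changed state, a lower share of steroidogenic cells with unequal changes, or such transcripts made or taken up by the sorted cells may each apply. They were not separated.

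The wild-type array 4, labelled female, carried Y-linked transcripts: Ddx3y at 2.70 and Eif2s3y at 2.70 stood apart from the other 3 female-labelled arrays, at −5.27 and −5.24 or below. A swap with another array is argued against, since 0 of the 7 male-labelled arrays had all 3 of Ddx3y, Eif2s3y and Kdm5d at the level of the other female-labelled arrays, although Uty alone was at that level, −6.68, in wild-type array 7. A mixture of equal parts male and female RNA is argued against too, since it would lower the Y-linked genes by 1 log2 unit and their mean difference from the male-labelled arrays was 0.063 with a spread of 0.30. A wrong sex label of this animal is a candidate explanation, as 3 of 3 Y-linked genes lay within or above the male-labelled range.

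Uty was at −6.68 in the wild-type array 7, labelled male, against −3.81 to −2.88 in the other male-labelled arrays. Spp1 was at 3.39 in the wild-type array 4, against 1.13 to 1.84 in the other wild-type arrays. In the wild-type array 3, the one wild-type array of slide 2, Mpped2 was at 5.38 against 2.14 to 3.34 and Prkd1 at 1.69 against −0.94 to 0.13. Atp6v0d2 was there at −4.88 against −6.69 to −5.93, but on none of the wild-type arrays was it above background, so these are background signals. Nckap5 was at −2.27 in the knockout array 3 against −1.03 to −0.89 in the other knockout arrays.

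Other ways of splitting the 11 arrays were drawn, 100 in all with the real one, keeping slide as a block. For the genotype comparison 2 of the 100 gave as many genes as the 173 observed. The other was a split that called 789 and set wild-type arrays 3, 5, 6 and 7 against the rest. On slide 2 that split compares wild-type with knockout arrays, and on slide 3 it sets arrays 5, 6 and 7 against array 4. Its calls therefore mix genotype with differences among wild-type arrays. The drawn splits need not keep the number of knockout arrays on each slide. Of the 18 that do, 1, the real one, gave as many genes and 1 as many lists, with a highest of 0 genes and 16 lists among the others, and 18 splits are too few for a share under 0.05. The count of 173 genes was 10 without wild-type array 3. For the gene lists 9 of 100 gave as many as the 17 observed, with a highest of 19. Some splits keep or reverse most of the genotype grouping and so carry its effect. Wild-type array 7 with knockout arrays 1 to 3 gave 17 lists. Within slides, the 16 lists came from wild-type arrays 1 to 3 with knockout array 4. The splits therefore do not give the number expected by chance, and chance cannot be excluded for the 17. The macrophage median alone reached 2.92 in size in 1 of the 100, the real split, with a highest of 2.72 among the others. That list had the largest median of the 29 in the real split. It was not set against the largest list of each other split, so this choice favours the real split. For sex, 0 genes were observed (limma; 1544 at an unadjusted p under 0.05), so every split, 100 of 100, gave as many, which says nothing about chance. The highest was 1315, for a split that set wild-type arrays 1 to 4 against the rest.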

How the results depend on the processing

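Leaving out wild-type arrays 3 and 4 together, adding sex without array 4 and the sex comparison without array 4 were chosen after seeing the data. The genotype comparison kept the direction of all 173 genes except for 1 gene without the slide block and 1 with normexp, over those genes each alternative tested, but the number past the threshold moved from 173 to 594 without the slide block, 469 with slide as a random block, 533 on slides 1 and 2 alone, 0 on slide 1 or slide 2 alone (3856 and 7489 at an unadjusted p under 0.05), 28 with sex beside slide, 11 over male-labelled arrays with slide and 267 without slide, 624 with normexp, 92 with median scaling, 403 over genes above background on all 11 arrays, 1920 with array weights, 33 without wild-type arrays 3 and 4, and 78 with sex beside slide and wild-type array 4 left out. The 173 genes were chosen on these same arrays, so their kept direction is no independent check. Slides 1 and 2 alone hold 4 and 3 arrays and give the same fold changes as the main fit. The count of 533 in place of 173 therefore comes from the estimate of the spread and its degrees of freedom. Leaving out an array of slide 3 likewise changes only the spread. The lone wild-type array of slide 2 is assumed to vary like the knockout arrays. The cause of the other shifts was not tested. With single arrays left out the count ran from 10, without wild-type array 3 and all among the 173, to 565, without wild-type array 4. Of the 173 genes, 147 were shared with the calls made without the slide block, 157 with slide as a random block, 160 with those on slides 1 and 2, 173 with array weights, 129 with normexp, 89 with median scaling, 108 over genes above background on all 11 arrays, 114 over male-labelled arrays without slide and 7 with slide, and 26 with sex beside slide. Quantile normalization gave 247, the percentile over bright probes 130, no filter 130, separate probes 149, a trend and robust prior 232, and outlier spots kept, the series table and a 2-fold minimum 173 each. The median log2 difference of all tested genes was −0.16, and moved to −0.022 with the percentile over bright probes and −0.29 with normexp, so single changes are relative to such shifts.

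A replicate block in place of slide gave 177 genes, of which 87 were among the 173, and a replicate block with slide 0 genes (limma; 3161 at an unadjusted p under 0.05). The deviations of same-numbered arrays from their group means correlated at 0.18, 0.22, −0.0077 and 0.18, and 1 of the 4 knockout arrays correlated best with the wild-type array of its own number, so a pairing was not established.

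Of the 20 genes with the highest and lowest fold changes, all 20 kept 1 direction under every alternative. They were chosen for 1 direction within slides 1 and 2, so fits resting on those slides alone could not reverse it. The other alternatives reused the same arrays, so the kept direction is no independent check. Of the 20, 3, Slc32a1, Car6 and Atp6v0d2, stayed past the threshold whichever array was left out, all 3 with wild-type signals at background on slides 1 and 2. The number of gene lists past the threshold moved from 17 to 0 with an estimated correlation, 8 with fry and 11 with a 2-fold minimum, and was between 13 and 21 in the other 34 of 37 alternatives. Of the 17 lists, 15 kept the sign of their median, and 6 (macrophage, lysosome, cell cycle, chemokine, complement and liver X receptor) passed with the preset correlation under every alternative. In the sex comparison 0 genes (limma; 1544 at an unadjusted p under 0.05) became 4 without wild-type array 4 and 3 without wild-type array 3, and 0 to 4 over all single arrays left out. The following values changed sign, and the cause was not tested. The fits on slide 1 alone, over male-labelled arrays with slide and without wild-type array 3 take the difference from slide 1 only. They give 1 estimate and are not separate checks, also where wild-type array 4 is left out with array 3. For Eng, 2.01 became −0.29 over male-labelled arrays without slide. For Inhba, 2.49 became −0.37 over male-labelled arrays without slide. For Egln3, −1.08 became 0.072 on slide 1 alone, over male-labelled arrays with slide and without wild-type arrays 3 and 4, and −1.61 to 0.072 when single arrays were left out. For Pfkl, 1.03 became −0.24 on slide 1 alone, over male-labelled arrays with slide and without wild-type arrays 3 and 4, −0.45 over male-labelled arrays without slide, and −0.24 to 1.50 when single arrays were left out. For Pax2, −0.30 became 0.32 over male-labelled arrays without slide, and for Sox2, 1.51 became −0.11 with normexp, but neither was above background on the wild-type arrays of slides 1 and 2, so these signs carry little meaning. For the ACTH and cAMP signalling list, 0.20 became −0.097 on slide 1 alone, over male-labelled arrays with slide and without wild-type arrays 3 and 4, −0.052 with sex beside slide, −0.34 over genes above background on all 11 arrays, −0.068 with array weights, −0.20 with sex beside slide and wild-type array 4 left out, and −0.097 to 0.35 when single arrays were left out. For the adrenal transcription factors list, −0.17 became 0.019 with slide as a random block, 0.12 on slide 1 alone, over male-labelled arrays with slide and without wild-type arrays 3 and 4, 0.011 on slide 2 alone and with the replicate block and slide, 0.032 with the replicate block in place of slide, 0.075 with quantile normalization, 0.027 with array weights, and −0.21 to 0.13 when single arrays were left out. For the cholesterol uptake, esterification and transport in the cell list, −0.054 became 0.12 without the slide block, 0.026 with slide as a random block, 0.56 on slide 1 alone, over male-labelled arrays with slide and without wild-type arrays 3 and 4, 0.28 with sex beside slide, 0.52 over male-labelled arrays without slide, 0.11 with the replicate block in place of slide, 0.16 with the replicate block and slide, 0.011 with normexp, 0.086 with quantile normalization, 0.081 with the percentile over bright probes, 0.39 with array weights, 0.32 with sex beside slide and wild-type array 4 left out, and −0.29 to 0.56 when single arrays were left out. For the endothelial markers list, 0.63 became −0.17 over male-labelled arrays without slide. For the erythroid markers list, −1.003 became 0.029 without the slide block. For the glucocorticoid-responsive genes list, 0.36 became −0.012 without the slide block, −0.050 with slide as a random block, −0.36 on slide 2 alone, −0.24 over male-labelled arrays without slide. For the gonadal somatic cell markers list, −0.27 became 0.47 without the slide block, 0.14 with slide as a random block, 0.17 on slide 2 alone, 0.13 over male-labelled arrays without slide, 0.0062 over genes above background on all 11 arrays, and −0.31 to 0.26 when single arrays were left out. For the hypoxia and glycolysis list, −0.050 became 0.022 on slide 1 alone, over male-labelled arrays with slide and without wild-type arrays 3 and 4, 0.032 with sex beside slide, 0.019 with normexp, 0.043 with quantile normalization and over separate probes, 0.086 with the percentile over bright probes, 0.030 with array weights, 0.055 with sex beside slide and wild-type array 4 left out, and −0.10 to 0.089 when single arrays were left out. For the kidney and liver markers list, 0.90 became −1.71 on slide 2 alone, −0.66 over male-labelled arrays without slide, and −0.55 to 2.60 when single arrays were left out. For the lipid droplet and neutral lipid turnover list, 0.26 became −0.18 to 0.54 when single arrays were left out. For the NRF2 and oxidative stress list, 0.21 became −0.26 on slide 2 alone. Dim signals limit the rest: Slc32a1, Car6, Atp6v0d2, Npy2r, Shh, Spi1, Sox2 and Pax2 were above background in 1 genotype at most on slides 1 and 2, and have at best bounds.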

Other observations

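No test was run on the values below, which were chosen after they were seen. The wild-type arrays differed among themselves in transcripts of the cortex and the medulla. Levels in wild-type arrays 1 to 7 were 5.87, 7.04, 7.86, 7.49, 3.84, 3.21 and 4.95 for Star, and −1.18, −0.58, −3.45, 0.54, −6.11, −5.32 and −5.46 for Cyp21a1, the 21-hydroxylase gene, which was not above background on arrays 3, 5, 6 and 7. In the same order they were 0.56, 1.94, −1.03, −1.11, 3.42, 3.78 and 3.40 for Th, a gene of catecholamine synthesis, and 5.94, 7.63, 5.61, 4.80, 9.12, 9.43 and 9.04 for the chromogranin gene Chga. Arrays 4 to 7 shared slide 3, so these differences also lie within 1 slide. Across all tested genes the array 4 correlated at 0.92 and 0.93 with the wild-type arrays 1 and 2 of slide 1, and at 0.86, 0.86 and 0.87 with its slide neighbours 5, 6 and 7 (Pearson, across genes, which are not independent replicates).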
